A study of Homo sapiens with 3 samples.

How the data were processed

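The data were CUT&Tag peak lists of 3 libraries from A2780 cells, a human ovarian carcinoma line: H3K27ac after the BPP peptide (BPP), H3K27ac in the control (CTR) and an IgG background library (IgG). Groups were taken from the sample titles, and each group had 1 library. The series design names a TAT peptide as the comparator in its RNA-seq; what the CTR cells of the CUT&Tag received was not given in the sources used here. Per the labels' protocols, frozen cells were thawed and a commercial CUT&Tag kit was used. Per the submitters' processing notes, fastp, Bowtie2 2.4.1 and deepTools 3.3.0 were used and the genome build was GRCh38.p13 (hg38). The peak caller, its settings and whether the IgG library served as a control during calling were not given in the sources used here.

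The authors deposited a separate peak list for each library, so peaks were not called on pooled samples. Each row gives a peak's chromosome, start, end and summit. The authors' score per peak equals 10 times the −log10 p cut to a whole number in every row. The authors' fold per peak is a ratio over a background that is not described. The deposited −log10 p-value and −log10 q-value per peak come from the authors' peak caller, and no −log10 p lay below 5 in any list. Median −log10 q was 7.11 in BPP, 7.18 in CTR and 2.50 in IgG, and median fold was 4.36, 4.64 and 4.23. The authors' per-peak values were used to rank and describe peaks within a list and, in alternatives, to filter each list at a fixed value, which need not be equally strict in each list. A peak missing from a list may lie just under the caller's threshold, and a deeper library passes more peaks, so presence in 1 list only is a statement about the lists. The number of reads per library was not given in the sources used here, so depth is unknown.

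Peaks on chromosomes 1 to 22 and X were kept, which left out 28 of 17869 BPP, 37 of 14873 CTR and 14 of 7715 IgG peaks. Peaks were called overlapping from 1 bp. Shares carry 95% Wilson intervals and differences of shares Newcombe intervals. These cover counting error only, treat peaks as independent and say nothing of the spread between cultures. Where a count was 0, the share that 3 counts would give was printed as the limit. Random shares come from 100 placements of each peak at a random position of its chromosome, drawn with fixed seeds. Peaks without a counterpart are those with no peak of the other H3K27ac list within 1 kb. The 10 equal parts of a list and its top peaks were taken by −log10 p. Domains joined peaks no more than 10 kb apart and were kept with at least 3 peaks.

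Genes came from an NCBI RefSeq gene table of assembly GRCh38.p14, with 1 row per gene and 19974 protein-coding genes on the chromosomes used. The design fixed before the data were examined asked for windows around transcription start sites and for a split of gene bodies into exons and introns. The table has no strand, transcripts or exons, so windows of 1 kb on either side of both gene ends were used instead, and a peak overlapping such a window is called a gene-end peak. Some gene-end peaks may therefore lie at the end of transcription. A window can also reach a neighbouring gene, and a peak of that gene then counts for both. Patch releases 13 and 14 of the build share chromosome coordinates. As a check, moving the windows by 50 kb lowered the gene-end share to 7.32% in BPP, 6.86% in CTR and 3.64% in IgG. All coordinates printed are those of peaks in the deposited lists, counted from 1 on GRCh38.

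Gene lists were fixed before the data were examined and hold 926 distinct genes, of which 921 matched a symbol in the table; BIM, C1orf43, CTGF, CYR61 and DDX58 did not. There were 25 lists and the study's own genes. For each list the BPP-only minus CTR-only count was placed among 10000 random lists, each with as many genes as the list has with a gene-end peak in either H3K27ac library, drawn from all protein-coding genes with a gene-end peak in either H3K27ac library. Percentiles are mid-ranks and describe these libraries; they are not p-values. Genes were named by a rule fixed before the data were examined. It takes BIN2, HDAC1 and RPS6, and in each H3K27ac library the 12 gene-end peaks with the highest −log10 q whose gene has no peak of the other H3K27ac list or IgG in its window or within 1 kb. It also takes up to 4 members of each list with a gene-end peak in 1 library only (or in both, where there are none), the 5 gene-end peaks with the highest −log10 q per library, and the 5 domains of greatest covered length per library. A peak over 2 genes names both, and genes without an approved symbol were passed over. Some genes that the rule takes are not reported here.

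Analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap step was checked against bedtools 2.31.1, with BPP peaks set against a simulated list. Counts were identical for overlap from 1 bp and for overlap of at least 50% of both peaks. Overlaps between the deposited lists were not checked in this way. On simulated data the overlap step recovered 59.5% where 59.4% of 17841 peaks had been planted. For lists of 20 genes with BPP-only genes drawn 5 times as often, 82.5% of 200 simulated lists exceeded the upper bound of the central 95%, and 2% of random lists lay outside it. Alternatives tried were stricter thresholds (−log10 q of at least 5, fold of at least 5), equal numbers of top peaks (as many as in the shorter H3K27ac list, or 5000), removal of peaks overlapping IgG, overlap of at least 50% of both peaks or a peak within 1 kb, windows of 500 bp or 2 kb, joining distances of 5 or 20 kb, joining of peaks within 1 kb and all sequences in the lists.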

Results

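Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was profiled by CUT&Tag in A2780, a human ovarian carcinoma cell line. CUT&Tag tethers a transposase to antibody-bound chromatin, so that DNA beside the mark is cut and tagged for sequencing. There were 3 libraries, 1 per group. The BPP library came from cells given the BPP peptide, which by the series design competes for a phosphorylation site of BIN2. The CTR library was the control with the same antibody, and the IgG library measured background with a non-specific antibody. On chromosomes 1 to 22 and X the deposited lists held 17841 BPP peaks covering 10.4 Mb, 14836 CTR peaks covering 8.76 Mb and 7701 IgG peaks covering 3.67 Mb. Median peak widths were 485, 494 and 457 bp. The number of reads behind each list was not given in the sources used here, so depth was unknown and the lengths of the lists were not read as a change in the mark. With 1 library per group no difference had a replicate check, and no p-value between conditions was computed. Shares are given with 95% Wilson intervals, which cover counting error only. Fold and −log10 q are the authors' values for each peak and were used to describe, rank and filter the peaks of each list. Where values of both lists are printed for the same place, their difference is not read as a change. Depth and the background of the fold are unknown.

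The title of the series names BIN2, HDAC1 and RPS6, and these genes were examined first. BIN2, which encodes a membrane-binding BAR-domain protein, had no peak within 1 kb of either gene end and none over its span in any of the 3 libraries. The nearest peaks lay 32.5 kb away in BPP (chromosome 12, 51248012 to 51248524), 41.6 kb away in CTR (chromosome 12, 51238791 to 51239413) and 205.6 kb away in IgG. HDAC1, a class I histone deacetylase, had 1 peak near its higher-coordinate end in each H3K27ac list, and the 2 peaks did not overlap each other, although by gene HDAC1 counts as marked in both. The BPP peak (chromosome 1, 32332544 to 32332875) had a fold of 3.23 and a −log10 q of 6.16. The CTR peak (chromosome 1, 32334543 to 32335149) lay 0.916 kb beyond the gene span, with a fold of 3.20 and a −log10 q of 4.89. No peak of any list lay at the other end of HDAC1, and IgG had 1 peak inside the gene (chromosome 1, 32320369 to 32320796). The gene table gave no strand, so the peaks near HDAC1 are not read as promoter peaks of this gene. RPS6, a protein of the small ribosomal subunit and a substrate of S6 kinase, had an H3K27ac peak at its higher-coordinate end in both lists and no IgG peak. Its BPP peak (chromosome 9, 19380099 to 19380818; fold 6.83, −log10 q 16.9) overlapped its CTR peak (chromosome 9, 19379891 to 19380585; fold 6.15, −log10 q 11.6).

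The main comparison asked which H3K27ac peaks were called in BPP-treated and in control cells. The peaks with the highest −log10 q at gene ends were at the same 5 places in both lists. They lay at SNX8 and EIF3B, at UFSP2, at FLCN, at UFD1 and CDC45, and at CDC25C and FAM53C. EIF3B is a translation initiation factor, FLCN encodes folliculin, CDC45 is part of the replicative helicase and CDC25C is a phosphatase of mitotic entry. The peak at SNX8 and EIF3B had a fold of 12.4 in BPP (chromosome 7, 2353941 to 2354836) and 11.5 in CTR (chromosome 7, 2353866 to 2354842). Folds at UFSP2 were 14.9 in BPP and 14.5 in CTR, and at FLCN 10.6 and 11.3. Across the genome, 8928 of 17841 BPP peaks overlapped a CTR peak by at least 1 bp (50.04%, 49.3 to 50.8). In the other direction 8849 of 14836 CTR peaks overlapped a BPP peak (59.6%, 58.9 to 60.4). The same peaks placed at random on their chromosomes 100 times overlapped in 0.728% and 0.887% on average. Merged, the lists made 23662 regions, of which 8770 held peaks of both libraries, 8909 of BPP only and 5983 of CTR only.

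Peaks called in both libraries were the stronger ones in each list. In BPP the median −log10 q was 10.0 for peaks overlapped by CTR and 5.66 for the rest, and the median fold was 4.84 against 4.00. CTR peaks gave a median −log10 q of 8.99 when overlapped by BPP and 5.63 when not, with folds of 4.83 and 4.43. With each list ranked by −log10 p and divided into 10 equal parts, overlap declined from 97.9% in the first part of BPP to 16.5% in the last, and from 93.0% to 26.9% in CTR. Among the 1500 peaks with the highest −log10 p, 27 BPP peaks (1.80%, 1.24 to 2.61) had no CTR peak within 1 kb, whereas 99 CTR peaks (6.60%, 5.45 to 7.97) had no BPP peak within 1 kb. Of these, 13 BPP peaks and 53 CTR peaks lay at gene ends. The difference between 6.60% and 1.80% was 4.80 percentage points, with a Newcombe interval from 3.40 to 6.28. Whether it exceeds the spread between cultures could not be tested with these libraries.

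**Figure D1:**
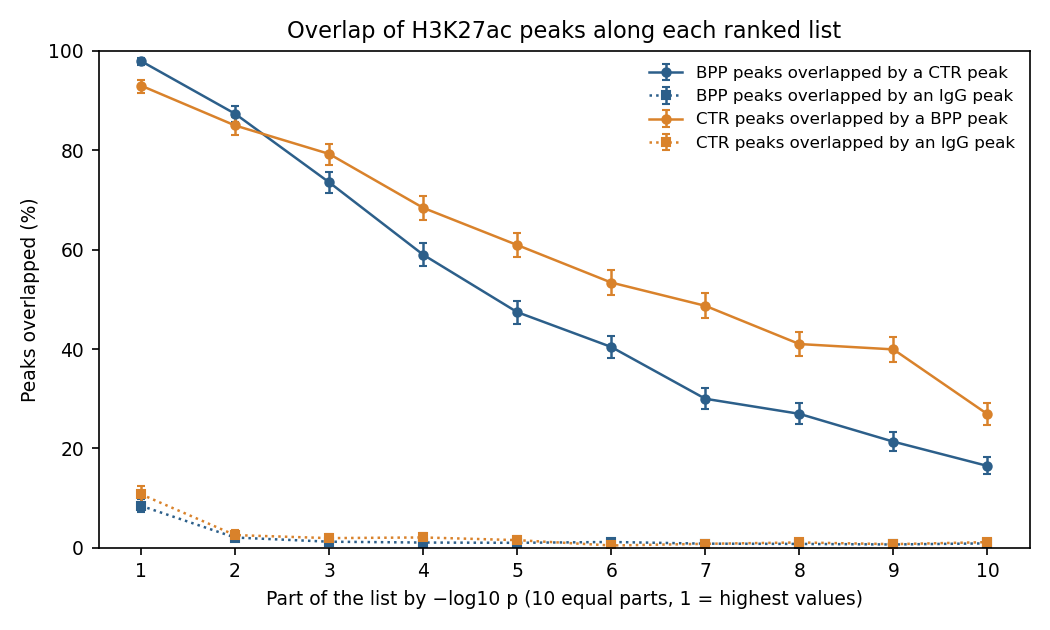
Percentage of H3K27ac peaks overlapped by a peak of the other H3K27ac list (solid lines) and by an IgG peak (dotted lines), in 10 equal parts of the BPP list and of the CTR list ranked by −log10 p (horizontal axis, part 1 has the highest values); bars are 95% Wilson intervals. Overlap between BPP and CTR falls from 97.9% to 16.5% of BPP peaks and from 93.0% to 26.9% of CTR peaks, and overlap with IgG is highest in the first parts, at 8.46% and 10.8%.

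Gene-end peaks found in the BPP library, with no CTR or IgG peak in the gene's window or within 1 kb, were led by the interval between GIT2 and ANKRD13A (chromosome 12, 109998868 to 109999406; fold 11.5, −log10 q 59.8). GIT2 is a GTPase-activating protein for ARF proteins. SLC35B1, a transporter of the endoplasmic reticulum, followed (chromosome 17, 49707937 to 49708291; fold 10.3, −log10 q 40.2). MAOA, which encodes monoamine oxidase A, had a BPP peak of fold 12.3 (chromosome X, 43654639 to 43654929; −log10 q 27.9). HYAL2, a hyaluronidase, had a peak of fold 4.18 (chromosome 3, 50321529 to 50322342), and POC5, a centriole protein, a peak of fold 10.6 (chromosome 5, 75717140 to 75717618). The next were ZSWIM2, SSR2, MYO1E, TMEM250, TIMM22, NOTCH2NLC and ARID4A, with −log10 q from 21.6 down to 19.7. SSR2 is a subunit of the translocon-associated complex, TIMM22 a mitochondrial inner-membrane translocase and ARID4A a subunit of SIN3 co-repressor complexes. NOTCH2NLC has near-identical copies in the genome, so the placement of its reads is uncertain.

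Gene-end peaks found in the CTR library, chosen by the same rule, were led by BCL6, a transcriptional repressor (chromosome 3, 187745494 to 187745842; fold 13.01, −log10 q 89.7). The next was the peak over NSUN2, an RNA methyltransferase gene, and SRD5A1, a steroid reductase gene (chromosome 5, 6632845 to 6633571; fold 9.39, −log10 q 53.8). VCP, an ATPase of protein quality control, had a CTR peak of fold 7.33 (chromosome 9, 35071665 to 35072669; −log10 q 48.1). SLC35E2B had a fold of 8.16, the peak over EEF1D and TIGD5 a fold of 5.70, and SLBP, which binds the stem-loop of histone mRNAs, a fold of 7.24. CNBP, a nucleic-acid-binding protein, had a CTR peak of fold 7.35 (chromosome 3, 129183150 to 129184244). FCSK, TTLL7, RPS7 and SLC25A6 were also among the 12, with folds of 8.73, 9.70, 7.79 and 7.16. The SLC25A6 peak (chromosome X, 1391724 to 1392791) lies in a region shared between the sex chromosomes, and SLC35E2B has a close paralog, so the placement of reads at both is uncertain.

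A further comparison asked where each list lay relative to protein-coding genes. BPP and CTR peaks lay within 1 kb of an annotated gene end far more often than IgG peaks. The share was 30.4% in BPP (29.7 to 31.1), 36.4% in CTR (35.6 to 37.2) and 4.87% in IgG (4.41 to 5.37), against 3.78%, 3.67% and 3.07% for peaks placed at random. Peaks called in both libraries were alike, with 42.5% of the BPP peaks and 42.4% of the CTR peaks at gene ends. Peaks with no counterpart within 1 kb differed between the lists, at 16.8% (15.97 to 17.6) for the 8235 in BPP and 25.5% (24.4 to 26.7) for the 5378 in CTR. The CTR share was 8.77 percentage points higher (Newcombe interval 7.36 to 10.2). Elsewhere inside genes lay 57.6% of the BPP peaks without a counterpart and 43.7% of those in CTR. In IgG, 53.2% of peaks lay outside genes, against 24.7% in BPP and 26.4% in CTR. The gene table gave no strand, transcripts or exons, so gene ends stand for start and end sites alike and exons were not separated from introns.

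**Figure D2:**
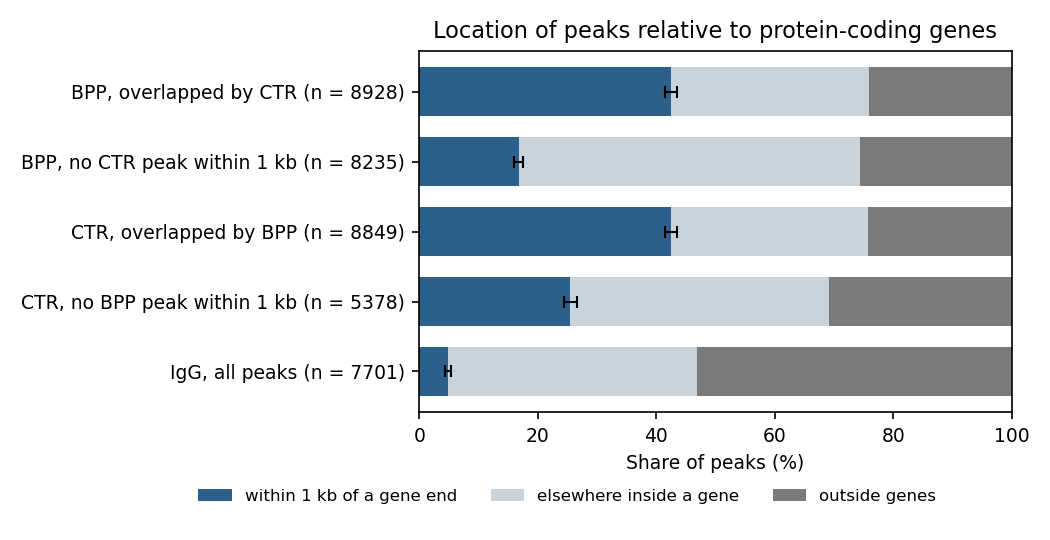
Share of peaks (horizontal axis, percent) within 1 kb of a protein-coding gene end, elsewhere inside a gene and outside genes, for BPP and CTR peaks with and without a counterpart in the other list and for all IgG peaks; black bars are 95% Wilson intervals of the gene-end share. The gene-end share is 42.5% and 42.4% for peaks called in both libraries, 16.8% for BPP peaks and 25.5% for CTR peaks without a counterpart, and 4.87% for IgG.

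Counted by gene, 4710 protein-coding genes had a gene-end peak in both H3K27ac libraries, 1405 in BPP only and 1513 in CTR only. This was 6115 of 19974 genes in BPP (30.6%, 30.0 to 31.3), 6223 in CTR (31.2%, 30.5 to 31.8) and 426 in IgG (2.13%, 1.94 to 2.34). Of the 2918 genes with a peak in 1 library only, 48.2% were on the BPP side (46.3 to 49.96). With windows of 2 kb the BPP side was the larger, with 1693 genes against 1535 (52.4%, 50.7 to 54.2). With peaks of fold 5 or more, 2256 genes had a peak in both libraries, 832 in BPP only and 1268 in CTR only. That threshold keeps 5964 of the 17841 BPP and 6012 of the 14836 CTR peaks, so it does not treat the lists alike, and counts at fold 5 carry this limit. The threshold of −log10 q of 5 keeps 13751 BPP and 11273 CTR peaks. Whether it is equally strict in both lists is not known. With the top 5000 peaks of each list the counts were 2046, 878 and 1167.

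Genes of chromatin acetylation were examined because the series title names HDAC1. Of 39 histone deacetylase and co-repressor genes, 14 had a gene-end peak in both libraries, 11 in BPP only and 4 in CTR only. This difference of 7 lay at percentile 98.8 of 10000 random lists of as many marked genes. On the BPP side were ARID4A (fold 8.06), the class II deacetylase HDAC5 (fold 6.35; chromosome 17, 44123809 to 44124221) and BRMS1 (fold 3.01), and on the CTR side was RCOR2, a CoREST subunit (fold 3.43). Of 25 acetyltransferase and bromodomain genes, 13 had a peak in both, 1 in BPP only and 5 in CTR only, at percentile 8.33. The CTR-only members included the acetyltransferase KAT8 (fold 5.64) and ING3 (fold 8.61), and the BPP-only member was BRD9 (fold 3.67). Of 46 replication-dependent histone genes, 42 core and 4 linker, 24 had a peak in both, 8 in BPP only and 2 in CTR only, at percentile 96.2. The 4 linker genes were all among those marked in both. H2AC7, H2BC7 and H3C4 shared a BPP peak of fold 4.07, and H3C6 had a CTR peak of fold 5.69. Histone genes are clustered and share peaks, so these counts are not independent. For the deacetylase list the percentile was 92.5 with windows of 500 bp, 83.2 with windows of 2 kb, 96.4 with peaks of fold 5 or more and 77.1 with the top 5000 peaks, each inside the central 95% of random lists. The acetyltransferase list lay outside it with windows of 2 kb (percentile 2.27) and with peaks of fold 5 or more (1.16), and the histone list with −log10 q of 5 or more (98.8) and with equal numbers of peaks (99.1). In the other settings both lists lay inside it. The acetyltransferase list was at percentile 48.6 with windows of 500 bp, and the histone list at 81.9 with peaks of fold 5 or more.

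Genes of translation and of the S6 kinase pathway were examined because RPS6 is a target of that kinase. Of 78 cytosolic ribosomal protein genes, 50 had a gene-end peak in both libraries, 10 in BPP only and 11 in CTR only (percentile 51.1). RPS7 (fold 7.79), RPL35 (fold 5.23) and RPL27A (fold 5.04) were on the CTR side and RPS15A (fold 5.38) on the BPP side. The share with a peak was 76.9% in BPP (66.4 to 84.9), 78.2% in CTR (67.8 to 85.9) and 5.13% in IgG (2.01 to 12.5). Of 41 genes of mTOR and S6 kinase signalling, 12 had a peak in both, 8 in BPP only and 9 in CTR only (percentile 43.2). CTR-only members included RRAGB (fold 8.68), the elongation factor kinase EEF2K (fold 5.32) and the initiation factor EIF4G1 (fold 4.24), and AKT1 had a BPP peak of fold 4.87. With the top 5000 peaks this list had 2 BPP-only and 9 CTR-only members and lay at percentile 1.81. That was its most extreme setting, and in the others its percentile ranged from 3.84 to 53.05.

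Among proliferation and survival genes, those marked in both libraries outnumbered those marked in either library alone. The same held for all protein-coding genes with a gene-end peak in either library, of which 61.75% had it in both. Of 47 cell cycle genes, 23 had a gene-end peak in both, 6 in BPP only and 8 in CTR only (percentile 34.5). TYMS, which encodes thymidylate synthase, had a BPP peak of fold 5.12, the spindle checkpoint kinase BUB1 a BPP peak of fold 4.83, and the helicase subunit MCM2 a CTR peak of fold 4.02. Of 33 cell cycle inhibitors and p53 targets, 12 were marked in both, 4 in BPP only and 6 in CTR only, among them PHLDA3 (CTR, fold 5.12), GADD45A (CTR, fold 5.97) and CDKN2D (BPP, fold 5.12). Of 41 apoptosis genes, 17 were marked in both, 6 in BPP only and 2 in CTR only (percentile 91.9). CYCS, the gene of cytochrome c, had a BPP peak of fold 5.73, and BIRC2, an inhibitor of apoptosis, a CTR peak of fold 6.82. Of 51 DNA repair genes, 23 were marked in both, 10 in BPP only and 6 in CTR only (percentile 88.4), and 5 also had an IgG gene-end peak. FANCE (fold 4.73) and RAD51C (fold 7.40) had BPP peaks, and DNA ligase I, LIG1 (fold 6.37), a CTR peak. Whether these peaks belong to a neighbouring gene reached by the window was not examined. No list in this paragraph lay outside the central 95% of random lists under any alternative.

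Ovarian carcinoma and epithelial markers had a gene-end peak less often than protein-coding genes as a whole in CTR, at 12.9% (5.13 to 28.9) against 31.2%. In BPP the share was 19.4%, with an interval (9.19 to 36.3) that includes the 30.6% of all genes. For mesenchymal and EMT genes the shares were 28.2% in BPP (16.5 to 43.8) and 23.1% in CTR (12.6 to 38.3), with both intervals reaching the share of all genes. Of 31 ovarian carcinoma and epithelial markers, 4 had a gene-end peak in both libraries, 2 in BPP only (MSLN, the gene of mesothelin, fold 3.89, and ELF3, fold 3.85) and none in CTR only. Of 39 mesenchymal and EMT genes, 7 were marked in both, 4 in BPP only and 2 in CTR only, including ITGA5 (BPP, fold 3.31), SPARC (BPP, fold 4.21) and TWIST1 (CTR, fold 4.09). Of 39 stem cell and oncogenic transcription factors, 4 were marked in both, 5 in BPP only and 1 in CTR only, at percentile 98.2. SALL4 (fold 3.59), POU5F1, a factor of pluripotency (fold 4.02), and ID3 (fold 2.48) had BPP peaks and ETV4 (fold 4.00) a CTR peak. This list returned to the central 95% with windows of 2 kb (96.0), with −log10 q of 5 or more (86.4), with peaks of fold 5 or more (55.1) and with equal numbers of peaks (92.5). Its difference of 4 equals the upper bound of the central 95% of random differences, and only the mid-rank percentile, which splits ties evenly, lies outside. By that percentile this list and the deacetylase list were the 2 of 25 outside, and by the bounds themselves only the deacetylase list, whose difference of 7 exceeds its bound of 6.

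Of 47 WNT, NOTCH and TGF-beta genes, 5 were marked in both libraries, 5 in BPP only and 3 in CTR only, with BMPR2 (BPP, fold 4.76), BMPR1A (CTR, fold 3.89) and AXIN1 (CTR, fold 3.55) among them. Of 46 growth factor receptor and MAPK genes, 11 were marked in both, 3 in BPP only and 4 in CTR only. The CTR-only members included BRAF (fold 6.71), MAPK8 (fold 5.65) and MAP2K1 (fold 4.40). Of 32 immediate early and stress genes, 13 were marked in both, 3 in BPP only and none in CTR only (percentile 90.3). The BPP-only members were DDIT3 (fold 3.38), IER2 (fold 2.64) and MAFF (fold 3.13), and with windows of 2 kb there were 8 against none in CTR only (percentile 99.6). The direction depended on the setting, with 3 in BPP only and 3 in CTR only with windows of 500 bp and with the top 5000 peaks, 1 and 1 with equal numbers of peaks, and 1 and 3 with peaks of fold 5 or more. Of 32 heat shock and folding genes, 18 were marked in both, 3 in BPP only and 5 in CTR only, including the chaperonin genes HSPD1 and HSPE1, which shared a CTR peak of fold 5.18. Of 41 interferon and antigen presentation genes, 17 were marked in both and 5 in each library only. IFIT2 (fold 3.86) was on the CTR side and IFNGR2 (fold 3.97) on the BPP side.

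Genes of glycolysis and hypoxia included 13 of 37 with a gene-end peak in both libraries, 3 in BPP only and 8 in CTR only (percentile 6.37). The glycolytic enzymes PGAM1 (fold 5.55), ENO1 (fold 4.36) and LDHA (fold 4.52) and the hypoxia-inducible factor HIF1A (fold 5.73) had CTR peaks. With peaks of fold 5 or more, none was on the BPP side and 6 were on the CTR side (percentile 0.655). This was the most extreme setting of the glycolysis and hypoxia list, with percentiles from 3.065 to 19.52 in the others. Of 31 housekeeping genes, 15 were marked in both, 3 in BPP only and 6 in CTR only (percentile 19.7), with VCP (fold 7.33) and RAB7A (fold 6.06) on the CTR side and POLR2A (fold 3.17) and UBB (fold 3.75) on the BPP side. With windows of 2 kb this list had 1 BPP-only and 8 CTR-only members (percentile 0.935). That was its most extreme setting, and in the others its percentile ranged from 19.15 to 38.61. How often some list would lie as far out in some setting by chance was not computed.

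Markers of other cell types had a gene-end peak less often than protein-coding genes as a whole in both H3K27ac libraries. For granulosa and germ cell markers in BPP (16.7%, 6.68 to 35.9), the interval includes the 30.6% of all genes. A gene-end peak in both, in BPP only and in CTR only was found for 1, 1 and 2 of 35 blood and immune cell markers, for 1, 1 and 1 of 34 neuronal markers, for 2, 0 and 1 of 27 hepatocyte markers and for 2, 1 and 1 of 28 muscle markers. Of 24 fibroblast and endothelial markers, ENG had a BPP peak (fold 2.83) and none had a CTR peak, which allows a share of up to 12.5% in CTR. With windows of 2 kb that list had 2 BPP-only members (percentile 97.9). This was its most extreme setting, and in the others its percentile ranged from 50 to 91.66. Of 24 granulosa and germ cell markers, 3 were marked in both and AMH in BPP only (fold 2.65). SPI1 (CTR, fold 4.05), PRF1 (CTR, fold 4.13) and GNLY (BPP, fold 3.74) were the blood markers with a peak in 1 library, NEFH (BPP, fold 3.83) and NEUROG2 (CTR, fold 4.28) the neuronal ones, TF (CTR, fold 4.88) the hepatocyte one, and CKM (CTR, fold 3.92) and TNNI3 (BPP, fold 2.92) those of muscle. The share of genes with a BPP peak was 5.71% for blood markers (1.58 to 18.6) and 5.88% for neuronal markers (1.63 to 19.1), against 58.1% for housekeeping genes (40.8 to 73.6).

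**Figure D3:**
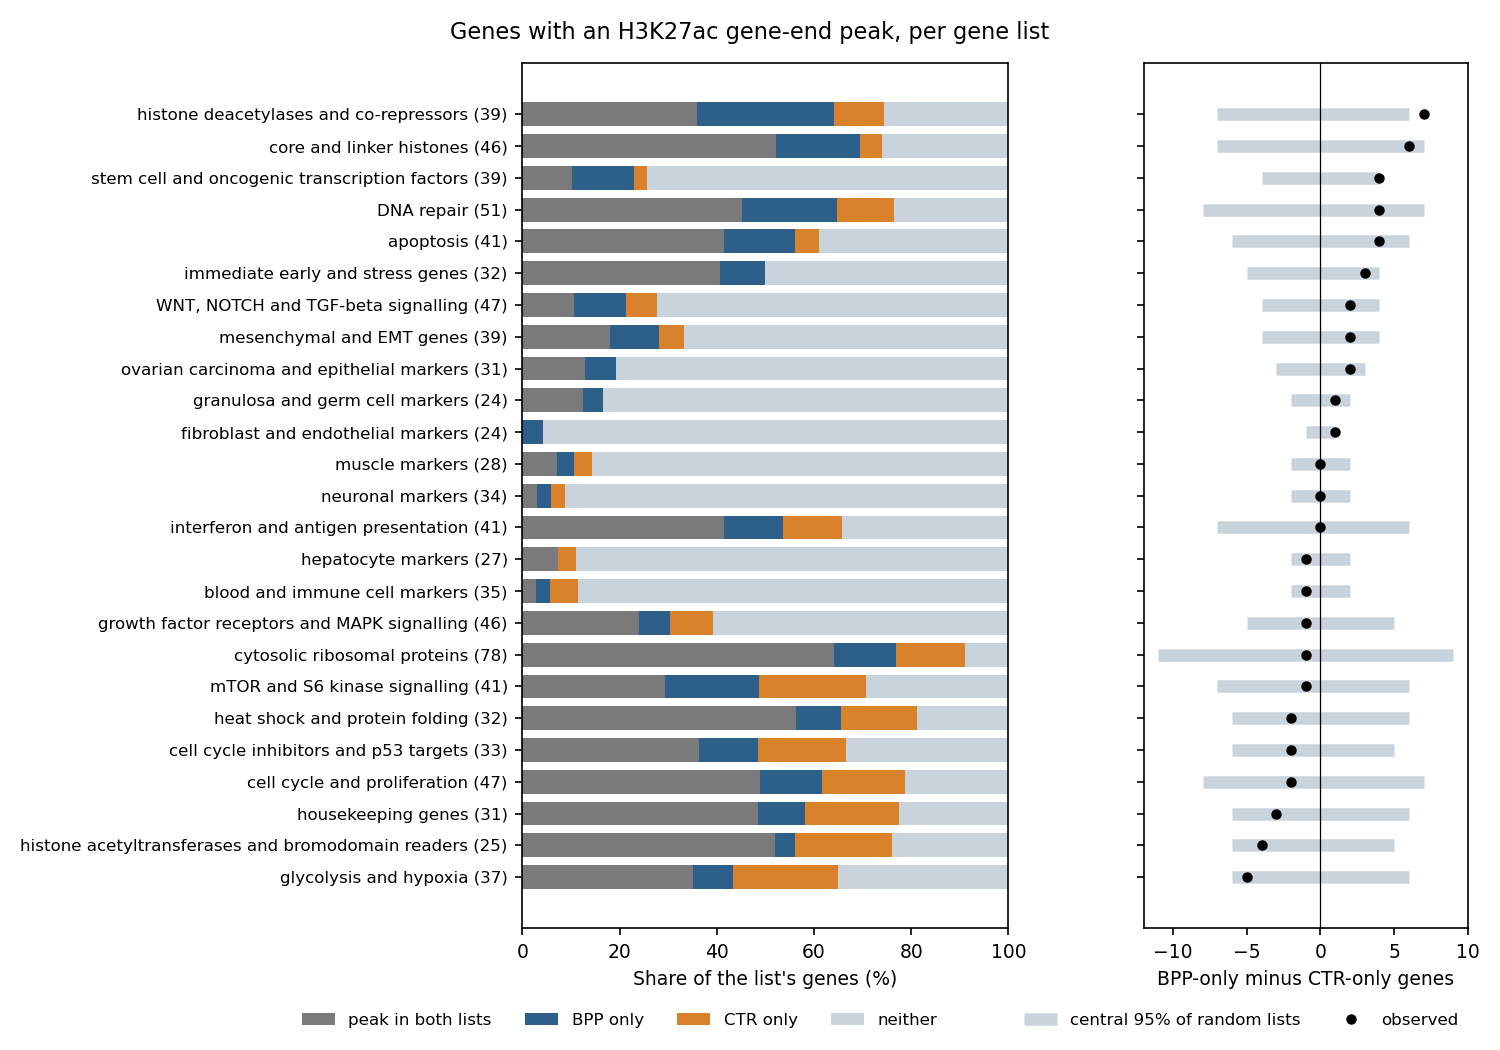
Left, share of the genes of each list (percent, number of genes in brackets) with a gene-end peak in both H3K27ac libraries, in BPP only, in CTR only or in neither; right, number of BPP-only minus CTR-only genes (points) with the central 95% of 10000 random lists (grey bars). The difference is 7 for histone deacetylases and co-repressors, beyond its grey bar, and 4 for stem cell and oncogenic transcription factors, at the end of its bar; no point but the first lies beyond its bar.

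Dense stretches of peaks were compared as domains of at least 3 peaks no more than 10 kb apart. The domain with the greatest covered length in both libraries lay over the non-coding genes DANT1 and DANT2 (chromosome X, 115843509 to 115899390 in BPP), with 20 BPP peaks and 17 CTR peaks. Next came a pair of domains over ribosomal RNA repeats that include RNA45SN1 and RNA45SN2 (chromosome 21, 8387802 to 8452225 and 8204824 to 8260929 in BPP), each of which also held an IgG peak. The fourth lay over MALAT1, an abundant nuclear long non-coding RNA (chromosome 11, 65470591 to 65508488 in BPP), with 8 BPP and 6 CTR peaks and no IgG peak. The fifth was MIRLET7BHG, the host of let-7 microRNAs, in BPP (chromosome 22, 46030622 to 46088048, 13 peaks) and NBPF1 in CTR (chromosome 1, 16607705 to 16645643, 8 peaks), and each was also a domain in the other H3K27ac list. The NBPF1 domain held an IgG peak and the MIRLET7BHG domain none. NBPF1 was the only protein-coding gene overlapped by these domains, and the non-coding genes were looked up after the domains were known. BPP had 773 domains, of which 228 overlapped a CTR domain (29.5%, 26.4 to 32.8), and CTR had 411, of which 231 overlapped a BPP domain (56.2%, 51.4 to 60.9). IgG had 17. Joining peaks no more than 5 kb apart gave 238 BPP and 116 CTR domains, and no more than 20 kb apart 1402 and 900. Ribosomal RNA repeats and NBPF genes have near-identical copies, so the placement of reads there is uncertain. Repeats were not annotated, and the placement of reads in the other domains, that over DANT1 and DANT2 included, was not checked.

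The IgG library gave the background of each measure. Of the BPP peaks, 325 overlapped an IgG peak (1.82%, 1.64 to 2.03), and of the CTR peaks 344 (2.32%, 2.09 to 2.57), against 0.282% for both at random. Regions with peaks of all 3 libraries numbered 270. The overlap was concentrated among the strongest peaks, at 8.46% of the first of the 10 parts of BPP (7.26 to 9.84) and 10.8% of that of CTR (9.30 to 12.5). Of the 20 peaks with the highest −log10 p, 15 in BPP and 17 in CTR overlapped an IgG peak. Those without IgG overlap in both lists lay at SERINC2 (fold 25.2 in BPP and 25.1 in CTR) and at the U1 small nuclear RNA genes RNU1-1 and RNU1-3, all chosen after their values were seen. With −log10 q of 5 or more, 337 IgG peaks were left, and 0.974% of BPP peaks and 1.33% of CTR peaks overlapped one.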

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

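No paired analysis was possible because each group has 1 library, and for the same reason none was left out. The alternative that uses only the outermost 5′ end of each gene was not run, because the gene table has no strand. Depth was unknown, which leaves list length and depth unseparated. All alternatives were planned. The alternatives covered peak counts, overlaps, gene-end shares, genes per library, gene lists, domains and the median −log10 q of shared and unshared peaks; where no value is given below for these, the gene lists excepted, counts moved by less than 1.5 times and shares and medians stayed within their intervals. Merged regions, the top 1500 peaks, gene families and RNA classes were not run under alternatives. CTR kept the higher gene-end share of the 2 H3K27ac lists in every setting run. Removing peaks that overlap IgG moved none of the peak counts, overlaps, gene-end shares, genes per library, domains or medians beyond these bounds.

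With −log10 q of at least 5, IgG kept 337 peaks, overlap was 52.1% of BPP and 62.8% of CTR peaks, IgG overlap 0.974% and 1.33%, and the gene-end share 34.5% and 41.6%. With a fold of at least 5 there were 5964 BPP, 6012 CTR and 1648 IgG peaks. Overlap was then 55.1% of BPP and 54.5% of CTR peaks, IgG overlap 2.52% and 2.73%, the gene-end share 42.9%, 48.4% and 7.28% in IgG, and 2256 genes had a peak in both lists and 832 in BPP only. With as many top peaks as the shorter list, overlap was 56.6% of BPP and 56.1% of CTR peaks, IgG overlap 2.04% of BPP, the BPP gene-end share 33.3%, and domain overlap 36.9% of BPP and 49.6% of CTR domains. With the top 5000 peaks, overlap was 62.5% of BPP and 62.1% of CTR peaks, IgG overlap 3.96% and 4.48%, the gene-end share 47.3%, 52.1% and 5.92% in IgG, and 2046 genes had a peak in both lists and 878 in BPP only. These settings keep fewer and stronger peaks by construction.

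Requiring overlap of at least 50% of both peaks gave 37.4% of BPP and 45.0% of CTR peaks, and 0.975% and 1.37% with IgG. Counting a peak within 1 kb gave 53.8% and 63.8%, and 2.58% and 3.21% with IgG, with median −log10 q of shared peaks at 9.60 in BPP and 8.65 in CTR. Windows of 500 bp gave gene-end shares of 25.4%, 32.5% and 3.27% in BPP, CTR and IgG, and windows of 2 kb 35.8%, 40.4% and 7.32%. Joining peaks no more than 5 kb apart gave 238 BPP domains (23.9% overlapping CTR) and 116 CTR domains (48.3% overlapping BPP); 20 kb gave 1402 (41.5%) and 900 (66.1%). With as many top peaks as the shorter list, BPP had 547 domains and CTR 411.

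The BPP-only part of the genes with a peak in 1 library only was 48.2% and ranged from 39.6% with a fold of at least 5 to 52.4% with windows of 2 kb. It was 40.5% with as many top peaks as the shorter list. For the gene lists, 87 of the BPP-only minus CTR-only differences under the alternatives were classed as moved and 87 as not moved. A further 1 lost its sign from outside the central 95%. The class of those not moved allows some change. It holds acetyltransferase genes, from -4 to -6 with a fold of at least 5, and histone genes, from 6 to 8 with −log10 q of at least 5. The 22 lists with a difference other than 0 gave 154 differences under the alternatives. Of these 154, 120 kept their sign, 23 went to 0 and 11 turned, the last in 8 lists. Ribosomal protein genes went from -1 to 4 with the top 5000 peaks, cell cycle genes from -2 to 3 with −log10 q of at least 5, and immediate early genes from 3 to -2 with a fold of at least 5. Of the lists outside the central 95%, that of stem cell and oncogenic transcription factors went to 0 with a fold of at least 5, and the deacetylase list kept its sign, down to 1 with the top 5000 peaks. Except where fewer peaks were kept by construction, the cause was not tested.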

Other observations

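The gene families and RNA classes below were chosen after the result was seen. So were the tests of the first pattern, of repeat-rich intervals and of always-active genes. The test of peak borders and those of the deacetylase list were written before their results were seen. Proteasome subunit genes were the most often marked of the 10 families examined, with a gene-end peak in both libraries at 38 of 50 genes, in BPP only at 2 and in CTR only at 3. Of 77 mitochondrial ribosomal protein genes, 44 were marked in both, 12 in BPP only and 6 in CTR only. Translation initiation factors had 34 of 55 in both, 4 in BPP only and 6 in CTR only, and splicing factor genes 22 of 33, 2 and 4. NADH dehydrogenase subunits had 19 of 46 in both, 7 in BPP only and 5 in CTR only. Zinc finger genes of the ZNF series had 177 of 517 in both, 45 in BPP only and 60 in CTR only, and solute carriers 61 of 386, 38 and 24 (percentile 99.1 of random lists). This was the most extreme percentile of the 10 families, with the others from 13.8 (ZNF) to 94.4 (HOX). How often some family would lie as far out by chance was not computed. HOX genes had 7 of 40 in both, 3 in BPP only and none in CTR only. Of 392 olfactory receptor genes, 1 had a peak in each H3K27ac library, and of 94 keratin-associated protein genes 1 in BPP and none in CTR.

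Small nuclear RNA genes, the RNA parts of the spliceosome, carried a peak within 1 kb of a gene end at 50 of 154 in each H3K27ac library (32.5%, 25.6 to 40.2), 48 of them in both, and at 2 in IgG (1.30%, 0.357 to 4.61). Transfer RNA genes were marked at 77 of 443 in BPP (17.4%, 14.1 to 21.2) and 64 in CTR (14.4%, 11.5 to 18.0), and at 2 in IgG. Long non-coding RNA genes were marked at 2334 of 18177 in BPP, 2215 in CTR and 1127 in IgG, and microRNA genes at 94 of 1911 in BPP, 81 in CTR and 9 in IgG. For ribosomal RNA genes IgG was close to the H3K27ac lists, with 8 of 49 against 11 in BPP and 10 in CTR. Many small RNA genes have near-identical copies, so the placement of their reads is uncertain.

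The first pattern is that BPP peaks without a CTR counterpart lay at gene ends less often than CTR peaks without a BPP counterpart. A weaker tail of a longer BPP list would remove the difference among strong peaks. Among peaks of each top 5000 with no peak of the other full list within 1 kb, it was 22.4 percentage points (17.1 to 27.5). This compares 51.3% of 710 CTR peaks with 28.8% of 572 BPP peaks. Weak peaks were thus left out of the shares, but matching used full lists of unequal length, so an effect of list length on matching remains. Among the top 1500, with 99 CTR and 27 BPP peaks matched in the same way, the difference was 5.39 points (-15.0 to 25.2), which is too imprecise to add to this. More IgG-like background in BPP would put its unmatched peaks outside genes, yet they lay over gene spans 5.20 points more often than those of CTR (3.59 to 6.81), while IgG lay over gene spans in 45.5%. Depth, signal-to-noise and caller settings of each library, and an effect of the peptide on acetylation inside genes, may each account for it and stay open with 1 library per group.

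The second pattern is that strong CTR peaks lacked a BPP peak more often than the reverse, with 99 against 27 of 1500. Peaks in repeat-rich intervals away from genes do not account for it, since at gene ends alone the difference was 5.26 points (3.22 to 7.45). Repeats were not annotated, so multi-copy sequence at gene ends was not tested. Peak borders shifted by 1 to 5 kb would leave a BPP peak nearby, but 19 of the 99 CTR peaks had one within 5 kb (19.2%, 12.6 to 28.0). Smaller shifts were not part of this test, because the 99 were chosen for having no BPP peak within 1 kb. Among 95 ribosomal protein and housekeeping genes with a gene-end peak in either list, 30 had it in 1 list only (31.6%, 23.1 to 41.5). Of these 30, 56.7% were in CTR (exact interval 37.4 to 74.5). Among all 2918 genes with a gene-end peak in 1 list only, 1513 were in CTR. The 30 genes are too few to tell whether BPP calls fewer gene-end peaks at genes that every cell uses. Without strand, gene-end peaks are not a count of promoters. Incomplete calling in BPP and loss of the mark at these sites therefore cannot be told apart.

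The third pattern is that histone deacetylase and co-repressor genes held more BPP-only than CTR-only members. The extra peaks of the longer BPP list do not account for it, because with BPP limited to as many top peaks as CTR the difference was still 7 (11 against 4, percentile 99.7), but it was 1 with the top 5000 peaks of each list (4 against 3, percentile 77.1). Chance among many lists remains open, since in 44.6% of 10000 redraws of all 25 lists some list lay as far out. The excess may therefore be no more than the most extreme of 25 draws, and no biological explanation was tested.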
